A study of Mus musculus with 2 samples.

How the data were processed

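Gene expression was measured in single CD45+ cells from the spinal cords of 4 C57BL/6 mice at day 15 after induction of experimental autoimmune encephalomyelitis (EAE), an autoimmune inflammation of the central nervous system. CD45 is the surface marker shared by leukocytes and microglia. Per the labels, 2 mice were untreated and 2 received an inhibitor, and each mouse carried its own antibody hashtag. The name, target, dose and schedule of the inhibitor are not given in the sources used here. Per the labels' protocols, the stained cells were pooled, about 28678 cells were loaded on 1 BD Rhapsody run, polyA RNA was captured on barcoded beads, and cDNA and hashtags were amplified by the TAS-Seq protocol. The mice are separate animals per the labels, so the spread between them is biological as well as technical. Pooling on 1 run gave all 4 mice the same library and sequencing. Group came from the hashtag named in each cell's column. The hashtag library, the other sample of the series, belongs to no group and was not analysed here.

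The authors deposited 1 matrix of whole-number counts for 28482 genes and 25461 cells, with no normalization of its values. The genome build was GRCm38 per the submitters' processing notes; the aligner, the counter and the use of strand are not given in the sources used here, nor is it stated whether a count is a molecule or a read. Genes were used under the symbols in the matrix. Genes with near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ifit1 and Ifit1bl1, Cstdc4 and Cstdc5, Tgtp1 and Tgtp2, the Klra family) could share reads, and their values are uncertain to that extent. Per the file's name, the counts had been through a step called DBEC, which on this platform stands for distribution-based error correction; its settings are not given in the sources used here. In the values, the 44 genes listed first had no nonzero count below 4, with a smallest nonzero count as high as 112 in S100a9, while 32.8% of all nonzero values in the matrix were 1. These 44 genes include Jchain, Igkc, Ltf, Camp, Lcn2, S100a8, S100a9, Retnlg, Mpo, C1qa, C1qc, Ccl5, Gzma, Cxcl2, Ifitm1, H2-Aa, H2-Ab1, H2-Eb1 and the haemoglobin genes. A value of 0 of such a gene can stand for a lower count that was set to 0 before deposit, so it is given as listed at 0, and no fold against such a group and no upper limit is given for it.

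Of the 25461 columns, 3943 (15.5%) carried more than 1 hashtag and entered no comparison. The 21518 cells with a single hashtag were filtered at a minimum of 200 genes, which removed 0 cells because the smallest number in the matrix was 500, and at most 20% mitochondrial counts, which removed 1014. Doublets of cells of the same mouse carry 1 hashtag. Their expected number, 1248 (6.09%), was computed from the hashtag doublets and the mice's shares of cells. Cells were scored by the share of hashtag doublets among their 50 nearest neighbours, and the 1248 highest were removed. The median score was 0.18 in hashtag doublets and 0.08 in other cells. This left 19256 cells, with 4312 and 4560 from the untreated and 5473 and 4911 from the inhibitor-treated mice.

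Clustering used log counts scaled to 10000 per cell, 2000 variable genes limited to scaled values of 10, 40 principal components, 20 neighbours and the Leiden method at a resolution of 1.0 (igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python 3.11.15; figures with matplotlib 3.10.9). The 23 clusters were named from 271 marker genes fixed before the data were examined, 8 of which have no row in the matrix. A name needed at least 3 of its markers detected in 25.0% of the cluster's cells, and no more markers of another class than of its own among the 10 genes with the largest fold. A subtype name of T cells also needed its own gene (Cd4, Cd8a, Trdc or Foxp3) detected at that share. This last condition was set after the data were seen, and cells it kept out of a subtype are given as T cells without subtype. Every class name in the text stands for cells that resemble that class in these markers.

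Shares of cells were tested with edgeR 4.0.16 (R 4.3.3), as a quasi-likelihood test on the number of cells per class and mouse with the mouse's kept cells as library size. Adjusted p-values are Benjamini-Hochberg values over the 16 classes, in which the T cell class overlaps its subsets. Shares of single mice have 95% Wilson intervals, which cover counting error only. For genes, counts were summed per mouse over all kept cells and per class with at least 30 cells in each mouse, filtered by filterByExpr, scaled by TMM and fitted with glmQLFit and glmQLFTest at the default estimation of the installed version. Log2 fold changes are inhibitor-treated over untreated with the standard error (SE), and adjusted p-values are Benjamini-Hochberg values within a class at a threshold of 0.05. CPM stands for a gene's count scaled to a class sum of 1000000, computed from the deposited counts. An exact permutation test of 2 against 2 mice cannot go below 0.333 two-sided, so single values are given per mouse.

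Lists of genes fixed before the data were examined (30 lists) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and at least 5 measured genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a class. They cover T cell programmes (Th17 effector, Th1 effector, regulatory T cell, T cell activation, proximal TCR signalling, naive or central memory, co-inhibitory receptors, cytotoxic granule), myeloid programmes (MHC class II presentation, inflammatory cytokine and chemokine, alternative activation and resolution, homeostatic microglia, disease-associated microglia, complement and Fc receptor), programmes of any cell (type I interferon, interferon-gamma, NF-kB targets, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosome, adhesion and chemokine receptor), handling and RNA quality (immediate-early and heat-shock, mitochondrial transcripts) and other cell types (myelin, astrocyte and neuron, endothelial and fibroblast, erythroid, neutrophil, B lineage). Each list's genes were also counted after adjustment over the list alone.

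Genes are named in the text by a rule set before the data were examined. For each fit these were up to 12 genes with the largest increase and 12 with the largest decrease among genes that passed, had both treated mice on the same side of both untreated mice and averaged at least 20 CPM, with the members of tested lists that passed, and Stap1. Where fewer than 10 passed, the 10 genes of at least 20 CPM with the smallest p are named as not having passed. Classes other than all cells together, neutrophils, T cells and CD4 T cells have at most 6. Variable segments of antigen receptors, Y-linked genes and Xist were left out, and a few genes that the rule or a list would name are not reported here. Examples within a list were chosen by their p after the values were seen. Positions of 111 of 115 named genes came from the GENCODE annotation of GRCm38.

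The gene test was tested on simulated counts with the real means and library sizes of each class and 200 changed genes. Each gene had the dispersion of the class trend, without the scatter of single genes around it. The changed genes were drawn from those above the median mean, so recovery in the real counts can be lower. Of 100 genes changed 4-fold the test recovered 100 in all cells together, neutrophils, T cells, CD4 T cells and microglia and 76 in B lineage cells. Of 100 genes changed 2-fold it recovered 60 in all cells together, 83 in neutrophils, 88 in T cells, 36 in microglia and 7 in B lineage cells, with 2 to 15 false calls per class. Replicates were not copies of 1 library: a chi-square test of their summed counts gave 54.6 per degree of freedom for the untreated and 266 for the treated pair. The alternatives tried were DESeq2 1.42.0 (Wald test and its size factors), no filter on low counts, the replicate number as a block, leaving out each mouse, and other doublet and cell filters. Further ones were cells thinned to 4000 counts, clustering resolutions of 0.5 and 2.0, TMM scaling or other denominators of shares, and an arcsine test of shares. For lists, an estimated correlation between genes and fry were tried. With 2 mice per group the estimated correlation rests on 2 degrees of freedom, so that test has little power. A list it did not call is not thereby shown to be unchanged. Thinning left out the cells below 4000 counts, 15.4% and 15.4% of the kept cells of untreated and 14.2% and 13.6% of those of treated mice. Chosen after the data were seen were the fits without marrow-type clusters (neutrophil, B lineage, progenitor and erythroid), the largest cluster of a class alone, removal of 2496 doublet calls, T cells and CD4 T cells without the cells that held Jchain, NK cells without those that held Ltf, list tests in CD8 T cells at the other resolutions, the crossed block, and the bias-adjusted deviances of edgeR.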

Results

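The question addressed was how an inhibitor given to mice with EAE altered the leukocytes of the spinal cord. Single-cell gene expression was measured in CD45+ spinal cord cells of 2 untreated and 2 inhibitor-treated C57BL/6 mice at day 15 after induction, pooled by hashtag on 1 run. After filtering, 4312 and 4560 cells of untreated and 5473 and 4911 of treated mice were kept. Their counts summed to 48425551 and 53497730 against 62034523 and 57872984. The median count per kept cell was 8186 and 8295 against 8250 and 8588, and the median number of genes 1475 and 1514 against 1330 and 1447. The median mitochondrial share was 3.78% and 4.16% against 2.40% and 3.42%. Doublet calls took 8.70% and 7.99% of cells against 3.20% and 5.03%. Treated mice had more cells, so more same-mouse doublets were expected, yet fewer were called. Removal thus differed by group and can shift shares and lists of other cell types.

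The 19256 kept cells formed 23 clusters. Neutrophils were the largest class (7232 cells), followed by T cells (7200 cells), of which 4667 resembled CD4 T cells. Neutrophil clusters were led by Retnlg, Mmp8 and Mmp9, genes of mature granules, by Ltf, Ngp, Camp and Lcn2, secondary granule genes of immature cells, by Il1b, Cxcl2 and Acod1, inflammatory genes, and by Fcnb and Chil3 in cycling precursors. T cell clusters resembled CD4, CD8, regulatory and gamma-delta T cells, and a cluster led by Xcl1, Klra6 and Cd160 stayed a T cell without subtype. Microglia (cluster 3), NK cells, B lineage cells, plasmacytoid and other dendritic cells, a monocyte and macrophage cluster led by Fn1 and F13a1, haematopoietic progenitors led by Mpo and Elane, and erythroid cells made up the rest. Cluster 19, led by C1qa, Apoe and Sparc, stayed unnamed. The CD45 sort sets which cells could enter, so shares are shares of sorted cells and not of the spinal cord.

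Neutrophils made up 21.7% ± 3.46 (SD, n = 2) of the cells of untreated and 50.4% ± 17.8 of those of treated mice, and T cells 49.4% ± 6.02 and 27.5% ± 13.1. In single mice the neutrophil share was 24.2% (22.9 to 25.5, 95% Wilson interval) and 19.3% (18.2 to 20.5) without treatment, and 63.1% (61.8 to 64.3) and 37.8% (36.5 to 39.2) with it. Gamma-delta T cells, a source of IL-17 in EAE, made up 4.13% ± 0.73 and 1.21% ± 0.21, regulatory T cells, which restrain the other T cells, 4.76% ± 0.90 and 1.91% ± 0.87, and T cells without subtype 4.63% ± 1.09 and 1.5% ± 0.67. None of the 16 classes passed the test with edgeR, 6 had an unadjusted p under 0.05, and limma on arcsine shares also called 0. The adjusted p was 0.105 for neutrophils (log2 fold 1.21 ± 0.57 SE), 0.072 for gamma-delta T cells (−1.78 ± 0.59), 0.072 for T cells without subtype (−1.63 ± 0.59), 0.105 for regulatory T cells (−1.32 ± 0.58) and 0.283 for all T cells (−0.85 ± 0.56). In 7 of the 16 classes both treated mice lay on 1 side of both untreated mice, and 2 against 2 mice do so by chance with a share of 0.333. CD4 T cells (31.0% ± 7.22 and 18.8% ± 11, adjusted p = 0.33), plasmacytoid dendritic cells (4.98% ± 3.69 and 2.08% ± 0.98, 0.105), NK cells (3.46% and 2.04%, 0.33), other dendritic cells (3.03% and 1.88%, 0.351), CD8 T cells (4.92% and 4.12%, 0.75), microglia (8.88% ± 4.37 and 7.04% ± 1.36, 0.739), monocytes and macrophages (1.88% and 2.10%, 0.794), B lineage cells (4.03% and 4.95%, 0.739), progenitors (0.436% and 0.874%, 0.274), erythroid cells (0.430% and 0.483%, 0.794) and the unnamed cluster (1.72% and 0.594%, 0.0873) also did not pass. With class counts scaled by TMM, 2 classes passed, neutrophils (log2 fold 2.18, adjusted p = 0.0036) and progenitors (1.88, 0.0223). The log2 fold of the neutrophil share lay between 0.80 and 1.54 with a mouse left out, and that of plasmacytoid dendritic cells between −1.87 and −0.19. Without treated replicate 2, T cells without subtype (−2.18, adjusted p = 0.0478) and the unnamed cluster (−2.55, 0.0478) passed.

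**Figure D1:**
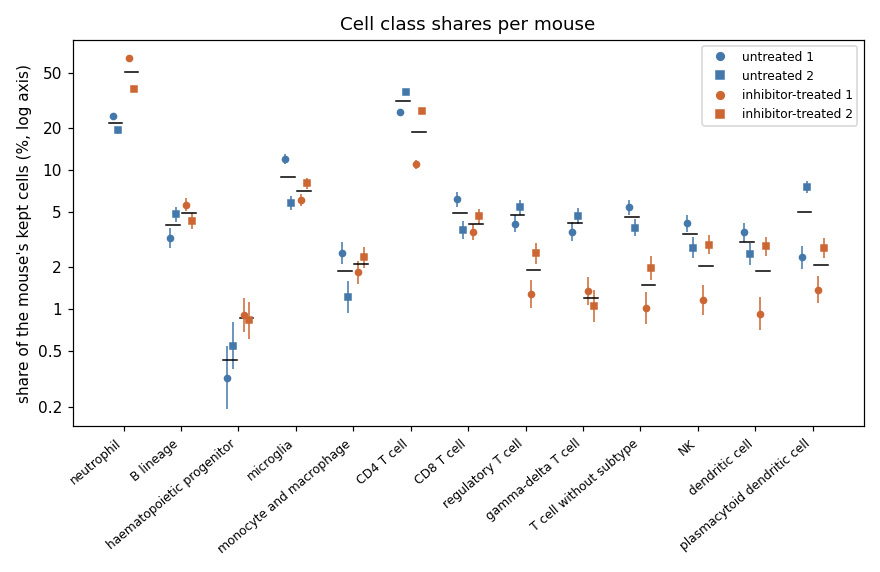
Share of each mouse's kept cells per class (percent, log axis), with 1 point per mouse (blue untreated, orange inhibitor-treated, circle replicate 1, square replicate 2), 95% Wilson intervals as vertical bars and group means as black lines, for 13 classes. Neutrophils lie at 24.2% and 19.3% in untreated and 63.1% and 37.8% in treated mice, and gamma-delta T cells at 3.62% and 4.65% against 1.35% and 1.06%.

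Because neutrophil, B lineage, progenitor and erythroid cells are also the cells of bone marrow, shares were recomputed without those clusters, a choice made after the data were seen. T cells then made up 67.3% ± 6.11 of the untreated and 63.0% ± 2.93 of the treated cells (log2 fold −0.10 ± 0.46, adjusted p = 0.983). Regulatory T cells (log2 fold −0.56, adjusted p = 0.464), gamma-delta T cells (−0.84, 0.326) and T cells without subtype (−0.87, 0.326) stayed negative and did not pass. CD8 T cells (0.58, 0.464) and microglia (0.50, 0.464) turned positive, and monocytes and macrophages were at 1.00 (0.326). Among the clusters, the B cell precursors of cluster 16 made up 0.976% and 3.12% of the untreated and treated cells (3.20-fold, adjusted p = 0.0871), and the Ltf- and Camp-rich neutrophils of cluster 2 4.37% and 12.3% (2.82-fold, 0.0917).

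Stap1, which encodes a signalling adaptor and is named in the title of the series, lies on chromosome 5 (86071746 to 86106125, plus strand, GRCm38). It was at 72.0 and 79.7 CPM in all cells of the untreated and at 107.7 and 83.2 CPM in those of the treated mice (log2 fold 0.33 ± 0.19, adjusted p = 0.567). Without the neutrophil, B lineage, progenitor and erythroid clusters its log2 fold was −0.21. In neutrophils, where it was at 125 and 122 CPM against 112 and 120, its log2 fold was −0.09 ± 0.11 (adjusted p = 0.977), and in T cells it was −0.13 ± 0.11 (1). In B lineage cells Stap1 was at 126 and 169 CPM against 62.0 and 62.7 (−1.24 ± 0.28, adjusted p = 0.569) and in microglia at 23.8 and 29.5 against 14 and 12.4 (−1.01 ± 0.31, 0.454). The B lineage value compares different mixtures of mature B cells and precursors. T cells of untreated mice held Stap1 at 82.8 and 83.0 CPM, and microglia of untreated mice held more T cell transcripts (both limits are given below). Whether Stap1 changed within microglia or B cells themselves was not tested. Stap1 passed in none of the 14 fits with edgeR.

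In all CD45+ cells together, 12 of the lists passed. Of these 2 rose, the neutrophil and the cell cycle list. The neutrophil list did so (12 of 12 members positive, median log2 fold 1.31, camera adjusted p = 5.27e-08, against adjusted p = 0.843 with an estimated correlation). All 12 members passed as higher when adjusted over the list alone, among them Ly6g (1.38 ± 0.37), Mmp9 (1.41 ± 0.36) and Lcn2 (1.33 ± 0.39). The regulatory T cell list fell (median −0.92, 7.12e-05, against adjusted p = 0.843 with an estimated correlation). Adjusted over the list alone, 6 of its 17 members passed as lower, among them Foxp3, the lineage factor (−1.30 ± 0.27), Ikzf2 (−1.20 ± 0.22) and Il10 (−1.80 ± 0.57), and 1 as higher, Ebi3 (1.07 ± 0.31), a subunit of heterodimeric interleukins. The interferon-gamma list fell with 0 of 23 members positive (median −0.42, 0.000165), the cytosolic ribosome list with 0 of 32 positive (−0.37, 2.67e-07), and the cell cycle list rose with 29 of 30 positive (0.30, 0.000165), each against adjusted p = 0.843 with an estimated correlation. Lists of T cells and antigen presentation also fell: co-inhibitory receptors (−0.68, 0.00251), T cell activation (−0.42, 0.00294), MHC class II presentation (−0.62, 0.00516), proximal TCR signalling (−0.55, 0.00534), Th1 effector (−0.39, 0.0101) and Th17 effector (−0.56, 0.0128), as did mitochondrial transcripts (−0.20, 0.0128). These calls too had an adjusted p = 0.843 with an estimated correlation. Adjusted over the list alone, Ptgs2 (1.11 ± 0.20) and Cxcl2 (1.35 ± 0.29) passed as higher in the inflammatory list, and Il7r, Tcf7 and Hsph1 as lower in theirs. The calls of the neutrophil, regulatory T cell, cell cycle and ribosome lists held without each mouse in turn. Without treated replicate 1 the other 8 ended (adjusted p from 0.0557 for TCR signalling to 0.637 for Th17). MHC class II (0.0537) and Th1 (0.0658) also ended without untreated replicate 1, and Th17 (0.23), TCR signalling (0.0955) and mitochondrial transcripts (0.449) without untreated replicate 2. Without the neutrophil, B lineage, progenitor and erythroid clusters, 7 of the 12 calls ended: neutrophil (0.0511), TCR signalling (0.0981), T cell activation (0.151), MHC class II (0.206), Th17 (0.228), co-inhibitory receptors (0.297) and Th1 (0.929). The other 5 were called in the same direction.

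No single gene of the 21103 tested in all cells passed with edgeR. At an unadjusted p under 0.05 there were 2131, and DESeq2 called 406 higher and 39 lower. The genes with the smallest p all had an adjusted p = 0.479. Trdc, the constant segment of the delta chain of the T cell receptor, was at 43.9 and 45.9 CPM in untreated and 17 and 19.9 CPM in treated mice (−1.29 ± 0.16), and 5830411N06Rik, which with Trdc leads the gamma-delta T cell cluster, had a log2 fold of −1.66 ± 0.21. Foxp3 was at 38.8 and 42.8 against 12.4 and 20.8 CPM. Ptgs2, which encodes the inducible cyclooxygenase, was at 18.0 and 17.3 against 44.1 and 31.8 CPM, Acod1, which makes itaconate, at 22.8 and 28 against 66.0 and 47.5 (1.16 ± 0.22), Gpr27 at 13 in both against 63.5 and 30.5 (1.85 ± 0.35) and Nhsl2 at 24.4 and 25.5 against 81.3 and 47.5 (1.37 ± 0.27). The chaperone Hsph1 (−0.98 ± 0.18) and the interferon-inducible Ifi208 (−0.86 ± 0.17) completed the set with Ikzf2. Without untreated replicate 1, untreated replicate 2, treated replicate 1 and treated replicate 2 in turn, 3, 2, 1 and 1535 genes passed.

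Within neutrophils, transcripts of the mitochondrial genome fell (13 of 13 members negative, median −0.51, camera adjusted p = 3.76e-06, against adjusted p = 0.904 with an estimated correlation). Of them 12 passed when adjusted over the list alone, such as mt-Nd2 (−0.66 ± 0.19) and mt-Cytb (−0.54 ± 0.17). The list serves as a sign of RNA quality as well. The homeostatic microglia list, markers of another cell type here, fell (12 of 15 negative, −0.57, 1.27e-05, against adjusted p = 0.904 with an estimated correlation), with Sparc (39.5 and 33.0 against 18.6 and 16.6 CPM), Fcrls and P2ry12 passing over the list alone, as did C1qa, C1qb and C1qc in the complement list. The cell cycle list fell (27 of 30 negative, −0.41, 0.00163). This call had an adjusted p = 0.904 with an estimated correlation, and ended without untreated replicate 2 (0.501, with a reversed sign) or treated replicate 1 (0.0607) and in the largest cluster alone (0.924). No gene of 14854 passed with edgeR, 735 had an unadjusted p under 0.05 and DESeq2 called 7, all lower. Genes with the smallest p were Cstdc5 (65.9 and 64.6 against 36.4 and 29.5 CPM, −0.98 ± 0.14), Sparc (−1.04 ± 0.16), Ctss (−0.74 ± 0.11) and C1qb (−0.95 ± 0.15), all at an adjusted p = 0.873, and Egr1, an immediate-early gene (−0.86 ± 0.14, 0.931). Gpr27 (0.54), C1qa (−1.94), Gbp2 (−0.68), the chemokine Ccl3 (−0.53) and Mpo (−0.65) followed at 0.973. In the largest cluster alone Cstdc5 had a positive log2 fold (1.35) on summed counts of 2 and 9 against 32 and 46, and Mpo was listed at 0 in both untreated mice. Without untreated replicate 1 there were 419 calls, without untreated replicate 2 19, and without treated replicates 1 and 2 1 and 4.

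In T cells, the regulatory T cell list fell (15 of 17 negative, median −0.31, camera adjusted p = 0.00159, against adjusted p = 0.784 with an estimated correlation), with Foxp3 (−0.74 ± 0.11), Ikzf2 (−0.60 ± 0.12) and Itgae passing when adjusted over the list alone. Foxp3 and Ikzf2 are among the 8 members that lead the regulatory T cell cluster, and the other 9, Itgae among them, had a median of −0.21. The neutrophil list rose (10 of 12 positive, 0.48, 0.00159, against adjusted p = 0.784 with an estimated correlation). The B lineage list, markers of another cell type in T cells, fell (0 of 10 positive, −0.56, 3.94e-08, against adjusted p = 0.784 with an estimated correlation), with Jchain, Igkc, Mzb1, Cd79a and Ighm passing over the list alone. Jchain (chromosome 5, 88519809 to 88527891, minus strand), which encodes the joining chain of polymeric immunoglobulins, was at 8.19 and 8.33 CPM in untreated mice and listed at 0 in both treated mice, and was the only gene of 16862 that passed with edgeR (adjusted p = 0.0352). This call rested on 2 cells, 1 of 1948 T cells of untreated replicate 1 (154 counts) and 1 of 2448 of untreated replicate 2 (192 counts), with Jchain listed at 0 in the 998 and 1806 T cells of the treated mice. The same 2 cells held 1238 and 3466 counts of Igkc, the immunoglobulin kappa constant segment (chromosome 6, 70726435 to 70726966, plus strand), and of the T cell genes Cd4 6 and 1, Trac 0 and 2, and Cd3e and Trbc2 0 in both. Over all T cells Igkc was at 84.1 and 178 against 16.6 and 22.1 CPM (−2.74 ± 0.33, 0.16). Without the 2 cells, a choice made after the data were seen, no gene passed, Igkc had a log2 fold of −0.24, and the B lineage list was still called (8 measured, median −0.39, 0.0167) with 0 members passing over the list alone. At an unadjusted p under 0.05 there were 691 genes, and DESeq2 called 2 higher and 21 lower. The regulatory T cell call ended without untreated replicate 2 (0.143), treated replicate 1 (0.0557) or treated replicate 2 (0.0516), and the neutrophil call without untreated replicate 2 (0.143) or treated replicate 1 (0.139). Other genes with small p were macrophage and antigen presentation genes, C1qc (−1.50 ± 0.18, 0.16), C1qa (−2.02 ± 0.34, 0.668), Cd74 (−0.84), Sparc (−0.85), Lgmn (−1.0) and Cst3 (−0.59), and Gm48161 (−0.66). Jchain did not pass with bias-adjusted deviances (0.106), a stricter filter on cells (0.0583) or thinned cells (0.302). Its adjusted p ranged from 5.89e-27 to 0.302 over the 13 alternatives in which it had a value. It had none with doublet calls kept, with double the number of calls removed or without the 2 cells. No gene passed with doublet calls kept or with double the number of calls removed, and without each mouse in turn (untreated replicates 1 and 2, treated replicates 1 and 2) 9, 4, 2 and 10 genes passed.

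In CD4 T cells, which exclude the regulatory T cell cluster, 2 genes of 15346 passed with edgeR, both lower. Igkc was at 134 and 242 against 9.49 and 15.4 CPM (−3.85 ± 0.34, adjusted p = 0.0403), and Jchain at 14 and 12.3 CPM against values listed at 0 (0.0403). Both calls rested on the 2 cells with Jchain, which are in this class and held 1238 of the 1468 and 3466 of the 3782 Igkc counts of the untreated mice. Without them no gene passed and Igkc had a log2 fold of −0.69 (adjusted p = 1). The B lineage list fell (9 of 10 negative, −1.19, camera adjusted p = 9.06e-10, against adjusted p = 0.39 with an estimated correlation), with Mzb1 and Cd79a passing besides these 2 when adjusted over the list alone. Without those 2 cells the list was called at 0.00315 (8 measured, median −0.54), with 0 members passing over the list alone. The regulatory T cell list fell (15 of 17 negative, −0.67, 1.76e-05, against adjusted p = 0.39 with an estimated correlation), with Foxp3 (39.7 and 33.5 against 16.4 and 18.2 CPM, −1.07 ± 0.20) and Ikzf2 passing over the list alone. Both list calls held without each mouse in turn. Genes with small p that did not pass were C1qa (−2.31 ± 0.24, adjusted p = 0.0865), the MHC class II genes H2-Aa (−2.12 ± 0.37), H2-Eb1 (−1.74 ± 0.32), H2-Ab1 (−1.41 ± 0.28) and Cd74 (−0.82 ± 0.17), and Cd8b1 (1.01 ± 0.17) and Cd8a (1.07 ± 0.21), which encode the CD8 coreceptor, with Cst3 and Gm48161, all but C1qa at 1.00. Neither gene passed with bias-adjusted deviances (Igkc 0.0543, Jchain 0.0773) or double the doublet calls removed (Igkc 0.999), and with doublet calls kept Igkc had a log2 fold of −0.69. The adjusted p ranged from 7.36e-95 to 1 for Igkc over 17 alternatives and from 3.81e-26 to 0.621 for Jchain over 14. Jchain had no value with doublet calls kept, with double the calls removed or without the 2 cells. Without untreated replicate 1, untreated replicate 2, treated replicate 1 and treated replicate 2, 3, 8, 6 and 17 genes passed.

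In CD8 T cells, 25 of 25 measured members of the type I interferon list had negative log2 folds, and the list fell (median −0.51, camera adjusted p = 2.37e-05, against adjusted p = 0.874 with an estimated correlation). Ifit1 (331 and 408 against 233 and 205 CPM, −0.75 ± 0.17) passed when adjusted over the list alone. Ifit1 and Ifit3 are among the 10 leading genes of the CD8 T cell cluster, and the other 23 members had a median of −0.51. At a clustering resolution of 2.0 a T cell cluster led by Ifit1, Ifit3 and Mx1 (260 cells, with CD4 T cells as the nearest class) took 24.2% and 35.7% of these CD8 T cells in untreated and 18.8% and 24.6% in treated mice, and the median in the CD8 T cells that formed there was −0.48 (adjusted p = 3.8e-06). The interferon-gamma list fell (20 of 23 negative, −0.26, 0.00972, against adjusted p = 0.874 with an estimated correlation), with the GTPase genes Tgtp2 (−0.81 ± 0.18), Igtp (−0.68 ± 0.19) and Tgtp1 (−0.81 ± 0.24) among those passing over the list alone. The neutrophil list (0.88, 0.00972) and the cell cycle list (18 of 25 positive, 0.37, 0.00972) rose. Both had an adjusted p = 0.874 with an estimated correlation. All 4 calls ended without untreated replicate 2 (type I interferon 0.185, interferon-gamma 0.185, cell cycle 0.349, neutrophil 0.628). Interferon-gamma ended without untreated replicate 1 (0.0792) or treated replicate 1 (0.44) too, cell cycle without treated replicate 2 (0.303), with double the doublet calls removed (0.0982) or with doublet calls kept (0.484), and neutrophil without treated replicate 1 (0.664). No gene of 10450 passed with edgeR, 573 had an unadjusted p under 0.05 and DESeq2 called 2. The genes with the smallest p, all at an adjusted p = 0.911, were Ifitm1 (267 and 161 against 29.1 and 65.2 CPM, −2.17 ± 0.37), Slfn1 (−0.67), Ly6c2 (−0.66), Tgtp2, Ifit1bl1 (−0.85) and Ifit1. Without untreated replicates 1 and 2, 61 and 18 genes passed, and 0 without either treated replicate.

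Among regulatory T cells the cytotoxic granule list rose (9 of 12 positive, 0.40, camera adjusted p = 0.0104, against adjusted p = 0.91 with an estimated correlation), with Ccl5 (324 and 320 against 604 and 520 CPM, 0.80 ± 0.16), Srgn (0.32 ± 0.09) and Gzma (listed at 0 in untreated replicate 1 and at 6.00 CPM in untreated replicate 2, against 27.2 and 121 CPM) passing when adjusted over the list alone. The myelin list, markers of oligodendrocytes, fell (4 of 5 negative, −1.40, 0.0104, against adjusted p = 0.91 with an estimated correlation). Both calls ended without untreated replicate 1 (0.233 and 0.0696) or treated replicate 2 (0.098 for both), myelin also without treated replicate 1 (0.239), and both with doublet calls kept (0.166). With double the doublet calls removed the cytotoxic granule call ended (0.198), Ccl5 had a log2 fold of −0.07 and myelin had fewer than 5 measured genes. Tnfrsf4, a leading gene of the regulatory T cell cluster, was at 879 and 893 against 1310.2 and 1358 CPM (0.59 ± 0.11), Tmx1 at 30.1 and 32.6 against 94.3 and 84.8, and the macrophage genes C1qc (−3.00) and Tgfbi (−3.24) had negative log2 folds, none of which passed. No gene passed with edgeR or DESeq2, and 400 had an unadjusted p under 0.05. Without untreated replicate 2, treated replicate 1 and treated replicate 2, 1, 47 and 97 genes passed.

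In gamma-delta T cells the interferon-gamma list fell (19 of 23 negative, −0.42, camera adjusted p = 0.016; adjusted p = 0.964 with an estimated correlation), with Gbp2 (254 and 265 against 119 and 91.5 CPM, −1.30 ± 0.24) passing when adjusted over the list alone. The call ended without untreated replicate 1 (0.147), treated replicate 1 (0.473) or treated replicate 2 (0.55). By edgeR 0 genes passed, 444 had an unadjusted p under 0.05 and DESeq2 called 1. Lcn2, a neutrophil granule gene, was listed at 0 in both untreated and at 58.6 and 55.3 CPM in the treated mice (adjusted p = 0.386), and the haemoglobin genes Hba-a1 and Hba-a2 were listed at 0 in both treated mice. Without the mice in turn (untreated 1 and 2, treated 1 and 2) 3, 4, 76 and 54 genes passed. In T cells without subtype the cell cycle list rose (18 of 20 positive, 0.65, 7.45e-05, against adjusted p = 0.816 with an estimated correlation), with Mki67 (29.5 and 25.9 against 90.1 and 64.2 CPM) and Mcm2 (33.9 and 22.4 against 84.7 and 72.1 CPM) nearest to passing over the list alone. The neutrophil list rose as well (9 of 12 positive, 0.0176, against adjusted p = 0.816 with an estimated correlation). Both ended without treated replicate 2 (0.165 and 0.666), and the neutrophil list without untreated replicate 2 (0.0902) or with double the doublet calls removed (0.317). Single genes passed in 0 cases with edgeR, 425 had an unadjusted p under 0.05 and DESeq2 called 4. Gzma, which encodes granzyme A, was at 122 and 141 against 36.1 and 19.8 CPM (−2.29 ± 0.38, adjusted p = 0.974). Without untreated replicate 2, treated replicate 1 and treated replicate 2, 1, 8 and 92 genes passed.

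In NK cells the neutrophil list, markers of another cell type here, rose (12 of 12 positive, median 1.85, camera adjusted p = 4.05e-08, against adjusted p = 0.726 with an estimated correlation). Of these, 9 members passed when adjusted over the list alone. Ltf, which encodes lactoferrin (chromosome 9, 111019271 to 111042767, plus strand), rose from 11.6 and 9.96 to 140 and 108 CPM (3.49 ± 0.39, adjusted p = 0.0424), the 1 gene of 9947 that passed with edgeR. Its counts came from few cells, 2 of 179 and 1 of 126 in untreated and 1 of 64 and 4 of 143 in treated mice. The Ltf call ended without untreated replicate 1 (0.356), untreated replicate 2 (0.0632) or treated replicate 1 (0.0598) and with thinned cells (0.0647). Without the cells that held Ltf, chosen after the data were seen, no gene passed, the call of NF-kB targets ended (0.0534) and the neutrophil list was still called (11 measured, median 1.82, 9.57e-06). Camp was listed at 0 in both untreated and at 145 and 34.6 CPM in the treated mice, and S100a8 (3.25 ± 0.58), S100a9 (3.31 ± 0.70), Cxcl2 (2.43 ± 0.38) and Cstdc4 (4.24 ± 0.92) did not pass. The cell cycle list rose (27 of 30 positive, 0.67, 5.61e-07, against adjusted p = 0.726 with an estimated correlation), with Cenpf (46.8 and 42.5 against 167 and 98.5 CPM, 1.55 ± 0.35) and Mki67 (0.80 ± 0.21) passing over the list alone. Lower lists were type I interferon (22 of 24 negative, −0.52, 0.0381; Isg20 alone), co-inhibitory receptors (−0.35, 0.0381; Cd5 alone), NF-kB targets (−0.53, 0.0415) and immediate-early and heat-shock genes (−0.28, 0.0488). These 4 had an adjusted p = 0.726 with an estimated correlation. The neutrophil and cell cycle calls held without each mouse. The other 4 ended without untreated replicate 2 (0.85, 0.342, 0.342 and 0.724 in the order above), treated replicate 1 (0.0665, 0.0665, 0.21 and 0.211) or treated replicate 2 (0.243, 0.309, 0.0803 and 0.25), and co-inhibitory receptors (0.0847) and NF-kB targets (0.108) without untreated replicate 1. With doublet calls kept, all but the cell cycle call ended (neutrophil 0.755, type I interferon 0.108, co-inhibitory receptors 0.131, NF-kB targets 0.129, handling 0.108). The handling call also ended with DESeq2's size factors (0.0522). Ltf had a log2 fold of −0.21 with doublet calls kept, and its adjusted p ranged from 5.68e-12 to 0.999 over 15 alternatives. It had no value without the cells that held it. DESeq2 called 2 genes, and without the mice in turn (untreated 1 and 2, treated 1 and 2) 0, 2, 0 and 63 genes passed.

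In microglia, 15 of 15 measured genes of the homeostatic list, which mark resting microglia, had positive log2 folds, and the list rose (median 0.57, camera adjusted p = 3.89e-05, against adjusted p = 0.766 with an estimated correlation). Of its members 5 lead the microglia cluster, among them Cx3cr1, P2ry12 and Tmem119, and the other 10 members had a median of 0.62, among them Fcrls (317 and 206 against 728 and 343 CPM), Sall1 (163 and 135 against 219 and 223) and Tgfbr1 (296 and 262 against 555 and 370). The alternative activation list rose (6 of 7 positive, 0.64, 0.0416, against adjusted p = 0.766 with an estimated correlation), with Chil3 (9.21 and 4.78 against 67.8 and 13.5 CPM) passing when adjusted over the list alone. Chil3 also leads the cycling neutrophil precursors and is among the 44 genes listed first, whose lower counts may have been set to 0. The neutrophil list was not called in microglia, and the source of Chil3 there was not tested. The disease-associated list, genes of microglia near lesions, was not called (0.13, 0.353), with Lpl at 44.8 and 47.9 against 130 and 61.9 CPM. The cytosolic ribosome list fell (0 of 32 positive, −0.64, 6.61e-11, against adjusted p = 0.766 with an estimated correlation). So did the adhesion and chemokine receptor list (15 of 20 negative, −0.64, 0.00194, against adjusted p = 0.766 with an estimated correlation), where 8 genes passed over the list alone, among them Itgb7 (−2.65 ± 0.46), Cxcr3 (−2.48 ± 0.52) and Cd44 (−1.34 ± 0.29), which lymphocytes also use to enter tissue. Cell cycle (−0.40, 0.00269), glycolysis (−0.36, 0.00275), oxidative phosphorylation (−0.33, 0.00322) and mitochondrial transcripts (−0.28, 0.00845) were the other lists that fell. These too had an adjusted p = 0.766 with an estimated correlation. The calls of the homeostatic, ribosome, adhesion and glycolysis lists held without each mouse. Alternative activation ended without any of the 4 (0.0653 to 0.277), with double the doublet calls removed (0.4) and with doublet calls kept (0.528). Cell cycle ended with double the doublet calls removed (0.801) and without untreated replicate 1 (0.67) or treated replicate 1 (0.181). Oxidative phosphorylation (0.0614 and 0.201) and mitochondrial transcripts (0.0614 and 0.108) ended without untreated replicate 2 or treated replicate 1.

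No gene of 14132 passed in microglia with edgeR, 1215 had an unadjusted p under 0.05, and DESeq2 called 2 higher and 108 lower. The genes with the smallest p, all at an adjusted p = 0.254, were genes of T cells: the T cell receptor constant segment Trbc2 (257 and 555 against 62.7 and 94.2 CPM, −2.37 ± 0.38), Cd6 (−2.94 ± 0.48), Tnfrsf18 (−2.42 ± 0.38), Ltb (−2.41 ± 0.38), Ctsw (−2.40 ± 0.40) and Nkg7 (−1.94 ± 0.32). The sum of 12 CD4 T cell markers in microglia was 1030 and 2603 CPM in the untreated and 317 and 455 CPM in the treated mice. The median count per microglial cell was 11574 and 10943 in untreated and 8121 and 9628 in treated mice. The T cell sums were lower in both mice of the treated group, in which the ribosome and adhesion lists fell and the homeostatic list rose (adjusted p = 0.766 for each with an estimated correlation). Without untreated replicate 1, untreated replicate 2, treated replicate 1 and treated replicate 2, 180, 0, 1 and 116 genes passed.

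**Figure D2:**
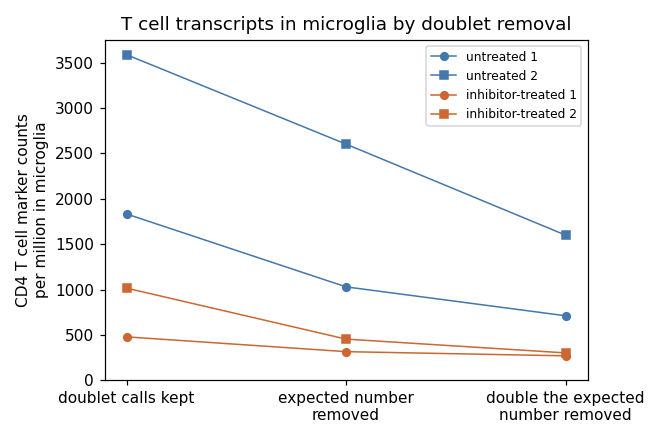
Summed CPM of 12 CD4 T cell markers in the microglia class, with 1 point per mouse, for doublet calls kept, the expected number of calls removed, and double that number removed. Untreated mice lie at 1030 and 2603 and treated mice at 317 and 455 with the expected number removed, and at 712 and 1601 against 271 and 303 with double that number removed.

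B lineage cells were held mostly by cluster 13 (mature B cells, 3.05% of untreated and 1.83% of treated cells) in untreated mice and by cluster 16 (precursors led by Vpreb3, Sox4, Ebf1 and Rag1, 0.976% and 3.12%) in treated mice, so values within the class compare different mixtures of the 2 clusters. The cell cycle list rose (29 of 30 positive, median 1.07, camera adjusted p = 3.94e-09, against adjusted p = 0.665 with an estimated correlation), with no member passing when adjusted over the list alone. Mcm6 was at 67.0 and 44.1 against 93.8 and 128 CPM, while Mki67 (586 and 45.3 against 612 and 460 CPM) and Top2a (432 and 24.1 against 519 and 399 CPM) were near the treated level in untreated replicate 1. Other lists that rose were oxidative phosphorylation (0.27, 0.0139) and the neutrophil list (0.54, 0.0299), both against adjusted p = 0.665 with an estimated correlation. The interferon-gamma list fell (22 of 23 negative, −0.58, 6.32e-05), with no member passing over the list alone, as did adhesion and chemokine receptors (−0.52, 0.00167; Itgb7 and Itgal passed when adjusted over the list alone), type I interferon (−0.47, 0.00626), ribosome (−0.25, 0.00626) and NF-kB targets (−0.29, 0.0157). The lists that fell also had an adjusted p = 0.665 with an estimated correlation. Of the 8 calls only that of the ribosome list (0.0267) was made in the same direction in the largest cluster alone. There cell cycle (adjusted p = 0.0267), type I interferon (0.162), NF-kB targets (0.762) and oxidative phosphorylation (0.807) had the opposite sign. Leaving out untreated replicate 2 ended the calls of cell cycle (0.143), adhesion (0.107), NF-kB targets (0.289), ribosome (0.143), oxidative phosphorylation (0.661) and type I interferon (0.0781). Interferon-gamma (0.0558), oxidative phosphorylation (0.0772), ribosome (0.246) and the neutrophil list (0.345) ended without treated replicate 1, and type I interferon without untreated replicate 1 (0.0536) or treated replicate 2 (0.0702). The neutrophil list reversed without untreated replicate 1 (0.175) and ended with doublet calls kept (0.488). No gene of 10923 passed with edgeR, 879 had an unadjusted p under 0.05, and DESeq2 called 11 higher and 40 lower. Itgb7 (140 and 170 against 29.5 and 39.3 CPM, −2.17 ± 0.30), Il4i1 (−2.26 ± 0.35), Fnbp1 (−1.58 ± 0.28), Tagap (−2.05 ± 0.36), Smcr8 (−2.83 ± 0.53) and H2bc11 (2.37 ± 0.44) had the smallest p (adjusted p = 0.569). Without the mice in turn (untreated 1 and 2, treated 1 and 2) 239, 11, 0 and 1 genes passed.

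In plasmacytoid dendritic cells, the producers of type I interferon, the inflammatory cytokine and chemokine list fell (0 of 7 positive, −0.74, camera adjusted p = 0.000618, against adjusted p = 0.589 with an estimated correlation), with Ccl4 (502 and 573 against 398 and 348 CPM, −0.53 ± 0.13), Ccl3 (108 and 78.7 against 52.3 and 26.7, −1.27 ± 0.36) and Cxcl10 (8.44 and 18.1 against 1.80 and 3.14) passing when adjusted over the list alone. The type I interferon (17 of 21 negative, −0.47, 0.00428) and interferon-gamma (17 of 21 negative, −0.30, 0.0121) lists fell too. Both had an adjusted p = 0.589 with an estimated correlation. The 3 calls ended without untreated replicate 2 (0.114, 0.217 and 0.139), and type I interferon also without treated replicate 2 (0.137). With edgeR 0 genes passed, 401 had an unadjusted p under 0.05 and DESeq2 called 4. The smallest p belonged to Ly6a (3813 and 3434 against 2823 and 2836 CPM, −0.36 ± 0.07) and Cd74 (−0.25 ± 0.06), and Il17rb was at 11.3 and 11.4 against 37.0 and 47.6 CPM. Without untreated replicate 2, treated replicate 1 and treated replicate 2, 4, 18 and 90 genes passed.

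In the other dendritic cells the complement and Fc receptor list fell (11 of 14 negative, −0.40, camera adjusted p = 0.0222), with C1qb and C1qc passing when adjusted over the list alone, as did homeostatic microglia genes (−0.69, 0.0222) and type I interferon genes (18 of 25 negative, −0.16, 0.0421). The adjusted p = 0.737 with an estimated correlation for the first 2 and 0.822 for type I interferon. The calls ended without untreated replicate 2 (0.157, 0.157 and 0.116) or treated replicate 2 (0.272, 0.0987 and 0.636), type I interferon without untreated replicate 1 (0.219), and homeostatic microglia with double the doublet calls removed (0.43). Ccl17, a chemokine for T cells (153 and 195 against 306 and 331 CPM, 0.87 ± 0.20), Ccl4 (0.79 ± 0.18) and Cxcl2 (1.06 ± 0.26) lay higher and Ifit2 (−1.43 ± 0.32) lower in treated mice, and none passed (adjusted p = 1.00). No gene passed with edgeR, 401 had an unadjusted p under 0.05 and DESeq2 called 1. Without untreated replicate 1, treated replicate 1 and treated replicate 2, 3, 30 and 247 genes passed.

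In monocytes and macrophages the immediate-early and heat-shock list, a sign of handling, fell (0 of 19 positive, −0.38, camera adjusted p = 0.00182, against adjusted p = 0.737 with an estimated correlation), as did NF-kB targets (−0.53, 0.0109; Bcl2a1d passed when adjusted over the list alone), glycolysis (−0.29, 0.0109), MHC class II presentation (11 of 14 negative, −0.43, 0.0206) and interferon-gamma (17 of 23 negative, −0.39, 0.0206). With an estimated correlation the adjusted p = 0.686 for glycolysis and 0.737 for the other 3. The neutrophil list rose (0.59, 0.00689, against adjusted p = 0.686 with an estimated correlation), with 5 members passing over the list alone. Without untreated replicate 1 all 6 ended (handling 0.0771, NF-kB 0.396, glycolysis 0.0877, MHC class II 0.669, interferon-gamma 0.829 with a reversed sign, neutrophil 0.065), and without treated replicate 1 the first 5 of these (0.0756, 0.621, 0.173, 0.797 and 0.764). The neutrophil call also ended without untreated replicate 2 (0.0564) or treated replicate 2 (0.0992). With double the doublet calls removed, NF-kB targets (0.158), glycolysis (0.188) and neutrophil (0.137) ended, and with doublet calls kept MHC class II (0.188) ended and neutrophil reversed (0.98). No gene passed with edgeR or DESeq2 and 345 had an unadjusted p under 0.05. S100a9 (591 and 271 against 1220 and 2898 CPM, 2.25 ± 0.40) and S100a8 (2.09 ± 0.39) had an adjusted p = 0.194, and Lcn2 (2.28 ± 0.49), Ly6i (−2.23 ± 0.47) and the T cell genes Trac (−2.27 ± 0.46) and Icos (−3.61 ± 0.79) followed. In this class the median mitochondrial share was 13.4% and 8.57% in untreated and 6.03% and 12.8% in treated mice. Bias-adjusted deviances, chosen after the data were seen, called 4 genes, and without the mice in turn (untreated 1 and 2, treated 1 and 2) 43, 11, 9 and 1 passed.

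Across the classes, 63 of 278 tests of lists were called, none of them with an estimated correlation (smallest adjusted p = 0.39). With 2 mice per group that estimate has little power, so its lack of calls does not show that the lists were unchanged. The calls themselves rest on the preset correlation, which was assumed and not measured. The fits overlap, since all CD45+ cells hold every class and T cells hold their subsets. Numbers of fits are therefore not numbers of separate sets of cells, as for the regulatory T cell list, called in all cells, T cells and CD4 T cells. The interferon-gamma list was called lower in 6 of 14 fits and higher in 0, with a negative median in 13, and the type I interferon list lower in 5 and higher in 0, with medians from −0.52 in NK cells to 0.11 in regulatory T cells. The cell cycle list was called higher in 5 and lower in 2, and the neutrophil list higher in 7 of 14 and lower in 0. Mitochondrial transcripts and ribosome were called lower in 3 each, adhesion and chemokine receptors, glycolysis, and the handling list in 2 each, and oxidative phosphorylation higher in 1 and lower in 1. NF-kB targets were called lower in 3. Of lists tested in fewer fits, the regulatory T cell list was called lower in 3 of 8, co-inhibitory receptors in 2 of 8, T cell activation, proximal TCR signalling and Th1 effector in 1 of 8, Th17 effector in 1 of 6, and the cytotoxic granule list higher in 1 of 8. MHC class II presentation was called lower in 2 of 6, the inflammatory and complement lists in 1 of 6, homeostatic microglia lower in 2 and higher in 1 of 6, alternative activation higher in 1 of 6, B lineage lower in 2 of 7 and myelin lower in 1 of 9. The naive or central memory list (medians −0.35 to −0.01 over 8 fits), disease-associated microglia (−0.19 to 0.13 over 6), astrocyte and neuron (−0.18 to 0.60 over 5), endothelial and fibroblast (−0.29 and −0.20) and erythroid (0.14 to 5.66 over 3) were called in none. Whether a list's change differed between classes was not tested.

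**Figure D3:**
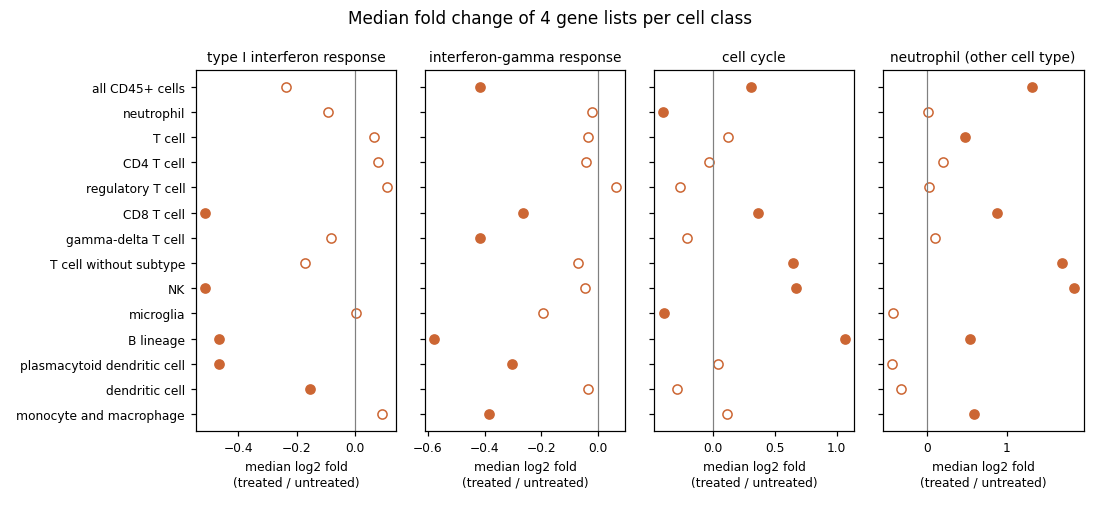
Median log2 fold change (treated over untreated) of the members of 4 lists (type I interferon, interferon-gamma, cell cycle and neutrophil) in each of the 14 fits, with filled points where the camera adjusted p was below 0.05. The type I interferon median is −0.51 in CD8 T cells and −0.52 in NK cells, and the neutrophil median is 1.31 in all cells and 1.85 in NK cells.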

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

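The tests of marrow cells, of fewer T cells, of free RNA, of doublets and of another clustering were chosen only after the data were seen, with what would count for doublets written before its result, while that of 1 mouse alone was fixed before. A signal outside the comparisons was the 3943 cells (15.5% of 25461) that carried more than 1 hashtag, which belong to no single mouse.

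The neutrophil share was 21.7% ± 3.46 in untreated and 50.4% ± 17.8 in treated mice (n = 2 each), and B cell precursors and progenitors also had higher means in treated mice, 3.12% against 0.976% and 0.874% against 0.436%, while erythroid cells, also cells of marrow, which lose the sorted marker CD45 as they mature, were at 0.483% against 0.430% (log2 fold 0.17 ± 0.64 SE). Bone marrow cells carried into the treated preparations may account for this, since spinal cords are taken from within bone. Precursor cells would then keep their number per remaining neutrophil, provided that neutrophils of untreated mice came with precursors at the ratio of marrow. If those held fewer precursors, carried-in marrow would raise the ratio instead. Precursors per 100 other neutrophils were 12.2 and 19.0 in untreated and 13.7 and 14.7 in treated mice, a log2 fold of −0.101 (95% interval −1.48 to 1.28). This leaves marrow cells open, because 4 mice give so wide an interval and because the ratio of marrow was not measured. Fewer T cells alone would leave neutrophils per microglial cell alike. These were 2.02 and 3.33 against 10.4 and 4.73, a log2 fold of 1.431 (−1.46 to 4.32), which leaves it open as well. Fewer T cells alone would also raise the shares of all other classes by the same factor. Mean shares were instead lower in treated mice for NK cells (2.04% against 3.46%), microglia (7.04% against 8.88%), plasmacytoid (2.08% against 4.98%) and other dendritic cells (1.88% against 3.03%). Those of B lineage cells, monocytes and macrophages, progenitors and erythroid cells were higher. The groups overlapped in each class named here as lower. The unnamed cluster was lower too (0.594% against 1.72%, adjusted p = 0.0873 with edgeR), without overlap of the groups. Its sign reversed with doublet calls kept and at a clustering resolution of 0.5, so these means do not decide it. An effect of the inhibitor on neutrophils cannot be told apart from these 2 in 4 mice and stays open, untested.

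T cell transcripts in microglia were at 1030 and 2603 CPM in untreated and 317 and 455 CPM in treated mice, and with doublet calls kept at 1833 and 3588 against 480 and 1016 CPM. Free RNA of the pooled run would be shared by all 4 mice, and the lowest untreated value was 2.265 times the highest treated value, which argues against it as the whole source. Removing double the number of doublet calls lowered the mean of the untreated mice by 36.34%, past the size set beforehand. It lowered that of the treated mice, of which that size took no account, by 25.65%. The calls rest on likeness in expression to hashtag doublets, so microglia that hold T cell transcripts for any reason would be called more readily. The falls therefore cannot tell doublets of a microglial cell and a T cell of the same mouse from other sources. Whether doublets make the difference between the groups stays open: the ratio of group means was 3.62 with doublet calls kept, 4.71 with the expected number removed and 4.03 with double that number removed, and the ratio of the lowest untreated to the highest treated value was 1.80, 2.27 and 2.35. A difference in the microglia themselves stays open too, untested.

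The type I interferon list in CD8 T cells had a median log2 fold of −0.51. If 1 mouse alone made it, leaving that mouse out would bring the median to 0 or above, and the highest median with a mouse left out was −0.257, without untreated replicate 2, which argues against a single mouse as the whole source. The call itself ended without that mouse (adjusted p = 0.185), and the adjusted p = 0.874 with an estimated correlation. At a clustering resolution of 2.0, where a T cell cluster led by Ifit1, Ifit3 and Mx1 took 24.2% and 35.7% of these cells in untreated and 18.8% and 24.6% in treated mice, the median in the remaining CD8 T cells was −0.48, and with doublet calls kept, where a like cluster formed, it was −0.28. A lower interferon response of CD8 T cells in treated mice remains a hypothesis from these data, and a different mixture of cell states stays open beside it.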

How the results depend on the processing

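The tests without marrow-type clusters, in the largest cluster of a class alone, with double the number of doublet calls removed, without the cells that held Jchain or Ltf, of lists at other resolutions in CD8 T cells, with the crossed block and with bias-adjusted deviances were chosen after the data were seen. Each result was counted once per alternative. Direction and side of the threshold were kept by 198 of 213 values of shares, 1818 of 2194 values of single genes and 409 of 682 values of called lists. Within 1.5 times of the reported count stayed 113 of 215 counts of genes and 82 of 151 counts of lists. This does not say that the calls were of the same genes or lists. Among the other values, 11 of shares reversed and 4 passed, and 102 gene counts and 69 list counts moved. Of single genes 354 values passed, 13 no longer did and 9 reversed, and of called lists 265 values ended and 8 reversed. Of those 265, 63 came from the estimated correlation and 63 from fry, each time the same 63 calls. Unless a cause is named, the cause was not tested. With 2 mice per group the spread within groups rests on 2 degrees of freedom before it is shared across genes. Of 100 genes changed 2-fold in simulated counts 60 were recovered in all cells, 83 in neutrophils, 88 in T cells, 71 in CD4 T cells, 36 in microglia and 7 in B lineage cells. Of 100 changed 4-fold all 100 were recovered in the first 5 of these and 76 in B lineage cells. The simulated genes had no scatter of dispersion around the trend, and the changed ones lay above the median mean. Recovery in the real counts can therefore be lower. A mouse left alone in its group was assumed to vary like the other group.

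DESeq2's Wald test called 445 genes in all cells, 7 in neutrophils, 23 in T cells, 17 in CD4 T cells, 2 in CD8 T cells, 1 in gamma-delta T cells, 4 in T cells without subtype, 2 in NK cells, 110 in microglia, 51 in B lineage cells, 4 in plasmacytoid and 1 in other dendritic cells. Without a filter on low counts edgeR called 83 genes in neutrophils, 97 in T cells, 64 in CD4 T cells, 8 in regulatory T cells, 26 in CD8 T cells, 11 in gamma-delta T cells, 18 in T cells without subtype, 36 in NK cells, 399 in microglia, 189 in B lineage cells, 21 in plasmacytoid and 19 in other dendritic cells and 12 in monocytes and macrophages. In these 13 fits the prior degrees of freedom became infinite, so that every gene was tested at the common spread. With bias-adjusted deviances the count was 0 in T cells, 0 in CD4 T cells and 4 in monocytes and macrophages.

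With an estimated correlation between genes, and with fry's directional test, 0 lists were called in each of the 14 fits, and fry's mixed test called 7. Without the neutrophil, B lineage, progenitor and erythroid clusters, the log2 fold of Stap1 in all cells was −0.21, and those of the CD8 T cell and microglia shares were 0.58 and 0.50. TMM scaling of class counts gave log2 folds of 0.56 for CD8 T cells, 2.18 for neutrophils, 0.47 for microglia and 1.88 for progenitors. In the largest cluster alone, Cstdc5 (1.35) and Mpo (7.42) had positive fitted values in neutrophils, for Mpo no fold since it was listed at 0 in both untreated mice (37 and 25 counts in the treated mice), 3 lists were called in B lineage cells, and there type I interferon (adjusted p = 0.162), NF-kB targets (0.762), cell cycle (0.0267) and oxidative phosphorylation (0.807) reversed.

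With doublet calls kept, Mpo reversed in neutrophils (0.29), as did Ltf (−0.21), Camp (−2.04) and Ngp (−1.05) in NK cells and S100a9 (−0.28) and S100a8 (−0.17) in monocytes and macrophages, where the neutrophil list reversed too (adjusted p = 0.98). The gene counts were then 0 in T cells, 0 in CD4 T cells, 3 in CD8 T cells and 0 in NK cells, and the list counts 5 in neutrophils, 4 in CD4 T cells, 0 in regulatory T cells, 1 in NK cells, 6 in dendritic cells and 11 in monocytes and macrophages. The share of the unnamed cluster had a log2 fold of 0.38 with doublet calls kept and 0.39 at a clustering resolution of 0.5. With double the number of doublet calls removed there were 0 gene calls in T cells and 0 in CD4 T cells, 0 list calls in regulatory T cells, 1 in T cells without subtype and 3 in monocytes and macrophages, and Ccl5 in regulatory T cells reversed (−0.072). Of single lists, 9 calls ended there, among them cell cycle in CD8 T cells (adjusted p = 0.0982) and microglia (0.801), alternative activation in microglia (0.4) and homeostatic microglia in dendritic cells (0.43), and 12 ended or reversed with doublet calls kept, among them the neutrophil list in NK cells (0.755). The stricter filter on cells gave 0 gene calls in T cells. Without the cells that held Jchain there were 0 in T cells and 0 in CD4 T cells, and without those that held Ltf 0 in NK cells. With cells thinned to 4000 counts there were 3 in T cells, 1 in CD4 T cells, 1 in CD8 T cells, 1 in gamma-delta T cells, 0 in NK cells and 1 in B lineage cells. A resolution of 2.0 gave 2 in CD8 T cells and a resolution of 0.5 gave 6 in NK cells. T cells without subtype did not form at a resolution of 0.5, so the NK class there may hold other cells than the main one. Classes that did not form at a resolution have no value there.

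The replicate numbers give no known pairing, and the correlation of same-numbered mice lay between −0.202 in monocytes and macrophages and 0.088 in microglia. With the replicate block 6 genes were called in T cells, 11 in CD4 T cells, 1 in CD8 T cells, 2 in T cells without subtype, 6 in NK cells, 116 in microglia, 6 in B lineage cells and 4 in monocytes and macrophages, with 0 lists in gamma-delta T cells and 2 in NK cells. In monocytes and macrophages the prior degrees of freedom became infinite with the block, so that every gene was tested at the common spread. The list calls that ended with the block were type I interferon, co-inhibitory receptors and NF-kB targets (adjusted p = 0.0522 each) and handling (0.0645) in NK cells, interferon-gamma in gamma-delta T cells (0.0643) and type I interferon in dendritic cells (0.113). Crossing the numbers in CD4 T cells, dendritic cells and monocytes and macrophages gave 0 lists in dendritic cells and 2 genes in monocytes and macrophages.

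Leaving out each mouse in turn gave from 1 to 1535 genes in all cells, 1 to 419 in neutrophils, 2 to 10 in T cells, 3 to 17 in CD4 T cells, 0 to 97 in regulatory T cells, 0 to 61 in CD8 T cells, 3 to 76 in gamma-delta T cells, 0 to 92 in T cells without subtype, 0 to 63 in NK cells, 0 to 180 in microglia, 0 to 239 in B lineage cells, 0 to 90 in plasmacytoid and 0 to 247 in other dendritic cells, and 1 to 43 in monocytes and macrophages. In 12 of these fits the prior degrees of freedom became infinite, so that every gene was tested at the common spread: those with 247 and 30 genes in other dendritic cells, 90 and 18 in plasmacytoid dendritic cells, 61 and 18 in CD8 T cells, 47 in regulatory T cells, 43, 9 and 1 in monocytes and macrophages, and 3 and 4 in gamma-delta T cells. The number of lists ranged from 6 to 15 in all cells, 3 to 6 in neutrophils, 1 to 7 in T cells, 2 to 5 in CD4 T cells, 0 to 4 in regulatory and in CD8 T cells, 0 to 1 in gamma-delta T cells, 0 to 2 in T cells without subtype, 2 to 4 in NK cells, 3 to 10 in B lineage cells, 1 to 6 in plasmacytoid and 0 to 5 in other dendritic cells, and 1 to 7 in monocytes and macrophages. Adjusted p ranged from 4.42e-10 to 0.501 for the cell cycle list in neutrophils, from 1.54e-08 to 0.345 for the neutrophil list in B lineage cells and from 0.000143 to 0.829 for the interferon-gamma list in monocytes and macrophages. Log2 folds of shares ranged from 0.80 to 1.54 for neutrophils, −1.44 to −0.43 for T cells, −1.50 to −0.22 for CD4, −1.87 to −0.91 for regulatory and −1.96 to −1.58 for gamma-delta T cells, −1.56 to −0.25 for NK cells, −1.87 to −0.19 for plasmacytoid and −1.70 to −0.095 for other dendritic cells, 0.044 to 0.61 for B lineage cells, 0.67 to 1.42 for progenitors, −0.58 to 0.16 for CD8 T cells, −0.76 to 0.28 for microglia, −0.27 to 0.77 for monocytes and macrophages, −0.013 to 0.37 for erythroid cells, −2.18 to −1.23 for T cells without subtype and −2.55 to −0.94 for the unnamed cluster, and in the last 2 the lowest value, without treated replicate 2, passed (adjusted p = 0.0478).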

Other observations

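The genes and clusters named here were chosen after their values were seen, and the tests of single clusters were not planned. The cytokines that define encephalitogenic T cells were measured in CD4 T cells, where Ifng was at 385 and 351 CPM in untreated and 356 and 420 CPM in treated mice (log2 fold 0.08 ± 0.12 SE), Il17a at 42.8 and 97.8 against 50.7 and 110 (0.21 ± 0.43) and Csf2, which encodes GM-CSF, at 14.3 and 9.39 against 7.27 and 10.3 (−0.39 ± 0.32). In gamma-delta T cells Il17a was at 286 and 548 against 269 and 324 CPM (−0.50 ± 0.30, adjusted p = 0.97 with edgeR). None of these passed. Over all CD45+ cells Il17a was at 17.4 and 52.4 against 11.4 and 30.6 CPM and Ifng at 138 and 140 against 57.7 and 130.

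Among neutrophil clusters, the Il1b- and Cxcl2-rich cluster 4 made up 3.97% ± 0.24 of untreated and 8.74% ± 4.56 of treated cells (n = 2, 2.20-fold, adjusted p = 0.167 with edgeR over 23 clusters), the Retnlg- and Mmp8-rich cluster 1 7.59% ± 2.82 and 18.5% ± 4.55 (2.44-fold, 0.125), the Stfa2l1-rich cluster 5 3.95% ± 1.5 and 7.70% ± 2.94 (1.95-fold, 0.267) and the cycling precursors of cluster 15 1.64% ± 0.51 and 2.74% ± 0.99 (1.67-fold, 0.333). Cluster 22, a neutrophil cluster led by the myelin genes Mobp and Mbp, made up 0.226% ± 0.009 and 0.453% ± 0.021 (0.309). The CD4 T cell cluster 9, led by Nrgn, Rgs16, Lta and Ifng, made up 3.70% ± 0.11 and 2.38% ± 2.17 (0.376) and the cycling CD4 T cells of cluster 18 1.86% ± 0.006 and 1.31% ± 1.14 (0.503). Over all CD45+ cells Jchain was at 2.92 and 30.2 CPM in untreated mice, at 23 CPM in treated replicate 1 and listed at 0 in treated replicate 2. In B lineage cells it was at 913 CPM in untreated replicate 2 and 458 CPM in treated replicate 1 and listed at 0 in the other 2 mice.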
